A study of Homo sapiens with 16 samples.

How the data were processed

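RNA of LNCaP cells was analysed in 16 samples, 2 replicates for each of 8 groups given by siRNA field (Scr, siOGT1, siOGT2, OSMI2) and agent (DMSO, AT7519). Per the labels, OGT was knocked down for 48 hours, DMSO or 0.5 μM AT7519 was given for 4 hours before harvest, and libraries were made from total RNA with a strand-specific kit. The dose and time of OSMI2, and whether scrambled siRNA was given with it, are not given in the sources used here. The deposited table of raw counts holds 1 whole-number count per gene and sample, and the submitters' processing notes name STAR, HTSeq and DESeq2 with hg19 and GRCh37, without versions or settings. The signal values of a separate deposited table are the authors' normalized counts. Checked against the counts, each equals the raw count divided by a median-of-ratios size factor per sample, with a largest relative deviation of 5.5e-10. The strand setting of the counting is not given in the sources used here.

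Gene IDs (60252) were matched to a gene name table by ID without version, which named 55528 and left 4724 without a name, and 55951 had a gene model in GENCODE v29. That annotation is built on GRCh38 and the counts on GRCh37, so it served for names, exon numbers and neighbours, and no coordinate is given. Total counts per sample were 107364119 and 68529552 (Scr), 147019364 and 56863068 (siOGT1), 53782868 and 48354151 (siOGT2), and 61077620 and 70876716 (OSMI2) with DMSO. With AT7519 they were 62420179 and 74725033, 59613623 and 89045835, 72461676 and 66662691, and 71158988 and 40216911. The common biological coefficient of variation was 0.110, and replicates within a group correlated with r of 0.983 to 0.991 across genes.

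The counts were analysed in R 4.3.3 with edgeR 4.0.16 on all 16 samples. Genes were kept by filterByExpr on the 8 groups (23830 of 60252), libraries were scaled by TMM, and a model with 1 mean per group was fitted by quasi-likelihood (glmQLFit, robust) and tested with glmQLFTest, two-sided. A gene was called at a Benjamini-Hochberg adjusted p under 0.05, and standard errors are the absolute log2 fold change over the square root of F. The 10 comparisons were AT7519 against DMSO in each of 4 arms, siOGT1, siOGT2 and OSMI2 against Scr under DMSO, and the difference of each of these 3 arms from Scr in the AT7519 response (interaction). Each gene list was tested with camera in limma 3.58.1 at a preset inter-gene correlation of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation. Of 29 lists written, 28 had tested members.

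Genes were named by a fixed rule. For AT7519 in Scr it took OGT and the 12 largest rises and 12 largest falls among called genes with a symbol, a mean log2 CPM of 3 or more and both AT7519 samples beyond both DMSO samples. It took the 5 largest of each direction for siOGT1, siOGT2 and OSMI2 against Scr, the 10 with the largest smaller fold for both siRNAs, and the 5 highest and 5 lowest differences for interactions. MYC, MCL1, HEXIM1, KLK3 and CDK9 were named in advance, and up to 4 members with the smallest adjusted p stand for each list, less some whose call rested on 1 library. Some genes that this rule took are not reported here. Overlaps between tested genes were found with GenomicRanges 1.54.1.

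For comparisons with the same controls, correlations of fold changes were set beside 20 simulated pairs of unchanged groups with independent replicates, and shared calls beside the overlap of independent lists. The single-exon comparison was tested by exact permutation of the agent over 8 and 8 samples, two-sided. The alternatives were RLE, upper-quartile and library-size scaling, DESeq2 1.42.0, limma voom, limma on log2 of the normalized values with 1 added, no low-count filter, a filter at a mean log2 CPM of 3, a fit of the compared groups only, a replicate block, a minimum fold of 2 and each sample left out. The spread of list medians between libraries was the SD within groups, pooled over all 8 groups (8 degrees of freedom) or over the 2 groups compared (2 degrees of freedom), with intervals from the t distribution. Random draws used the seed 20240501. The tests were tried on simulated data with independent replicates, in which genes were raised or lowered and a list raised by known folds. Between comparisons, 21.9% to 37.7% of genes changed 1.5-fold were called, and 72.1% to 75.9% of those changed 4-fold. Unchanged genes made up 3.7% to 6.9% of calls. Splicing, isoforms and allele-level values were not analysed here, and sequence reads were not used here.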

Results

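RNA of LNCaP prostate cancer cells was sequenced in 16 libraries that made 8 groups of 2. The arms were a scrambled siRNA (Scr), 1 of 2 siRNAs against OGT (siOGT1 or siOGT2), and OSMI2, a small-molecule inhibitor of OGT. The labels list OSMI2 in the siRNA field, and whether its cells also received scrambled siRNA is not given in the sources used here. Each of these 4 arms was treated with DMSO or with AT7519, an inhibitor of cyclin-dependent kinases. The series title concerns CDK9 activity and splicing, and the design asks how the AT7519 response looks with and without OGT. Gene counts do not measure splicing. The libraries held 40216911 to 147019364 counts. The highest total was that of siOGT1 replicate 1 under DMSO and the lowest that of OSMI2 replicate 2 with AT7519. Of 60252 genes in the table, 40417 had a count and 23830 were tested. Agent separated the samples on the first principal component (52.8% of variance), with DMSO samples at -78.1 to -68.3 and AT7519 samples at 50.3 to 91.5. Nothing in the labels says that replicates came from separate cultures, so p-values measure the spread between these samples, which may be technical.

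OGT (ENSG00000147162), which encodes the O-GlcNAc transferase that both siRNAs target, stood at 274 and 263.4 CPM (counts scaled to the library total times its TMM factor) in the Scr samples under DMSO. It stood at 20.7 and 14.6 CPM in siOGT1, at 36.0 and 29.8 CPM in siOGT2, and at 349.4 and 335.9 CPM in OSMI2. With AT7519 the values were 255.5 and 314.3 CPM in Scr, 11.01 and 10.98 CPM in siOGT1, 29.3 and 33.8 CPM in siOGT2, and 421.5 and 407.5 CPM in OSMI2. Against Scr under DMSO, OGT fell 15.1-fold with siOGT1 (log2 fold change -3.91, SE 0.14, adjusted p = 3.48e-11) and 8.16-fold with siOGT2 (-3.03, SE 0.14, adjusted p = 1.35e-09), and its value in OSMI2 was 0.35 (SE 0.13, adjusted p = 0.168). OGA (ENSG00000198408), which encodes the enzyme that removes O-GlcNAc, fell 6.54-fold with siOGT1 (-2.71, SE 0.23, adjusted p = 3.87e-05) and 6.01-fold with siOGT2 (-2.59, SE 0.23, adjusted p = 1.79e-04). In OSMI2 the value of OGA was -0.42 (SE 0.22, adjusted p = 0.406). OGA stood at 309.7 ± 29.8 CPM (SD, n = 2) in Scr, 47.1 ± 16.5 in siOGT1, 51.5 ± 15.2 in siOGT2 and 231.9 ± 8.51 in OSMI2. These values come from edgeR quasi-likelihood tests, two-sided, with 8 residual degrees of freedom and 2 libraries per group, as do the adjusted p-values of all comparisons below.

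**Figure D1:**
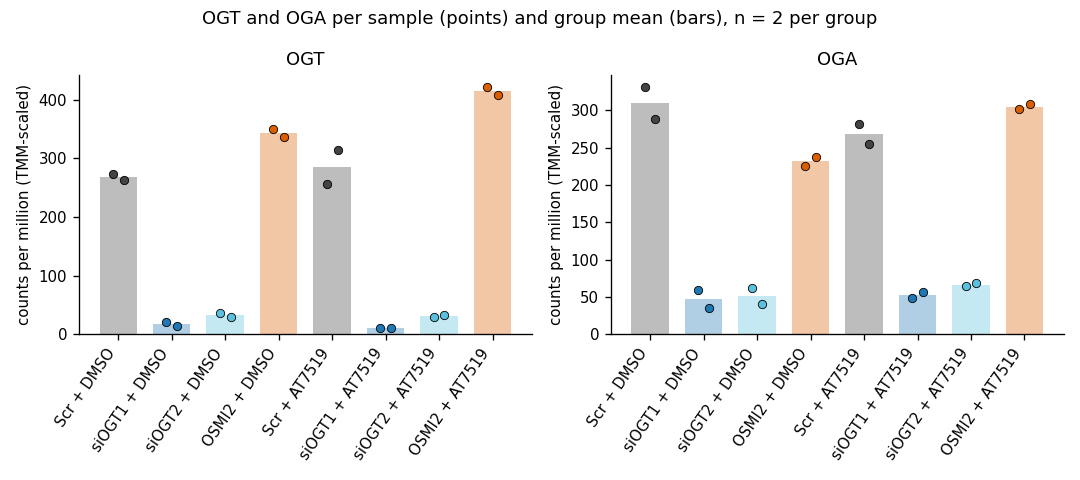
CPM of OGT and OGA in each of the 16 libraries, grouped by arm and agent, with 1 point per library. OGT fell 15.1-fold with siOGT1 and 8.16-fold with siOGT2 under DMSO.

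AT7519 in Scr cells changed genes in both directions. CCNL1 (ENSG00000163660), which encodes the splicing-associated cyclin L1, rose from 92.0 ± 4.31 to 421 ± 32.8 CPM (log2 fold change 2.19, SE 0.11, adjusted p = 1.64e-11). ZC3H12A (ENSG00000163874), which encodes an mRNA-degrading endonuclease, rose from 35.9 ± 2.01 to 140.6 ± 25.2 CPM (1.97, SE 0.24, adjusted p = 3.36e-05). SOWAHB (ENSG00000186212), an ankyrin-repeat gene with a single exon, fell from 27.0 ± 0.80 to 2.09 ± 0.87 CPM (-3.71, SE 0.20, adjusted p = 4.92e-11). IRF2BP2 (ENSG00000168264), which encodes a transcriptional corepressor, fell from 35.7 ± 2.81 to 4.58 ± 0.97 CPM (-2.97, SE 0.16, adjusted p = 3.21e-11). GID4, a substrate receptor of a ubiquitin ligase, fell from 25.3 ± 1.11 to 3.19 ± 0.28 CPM (-2.99, SE 0.13, adjusted p = 2.21e-12). SOWAHC, a relative of SOWAHB (-2.87, SE 0.22), FAM200C, a domesticated transposase gene (-2.85, SE 0.23), the zinc finger gene ZCCHC24 (-2.66, SE 0.16) and IGIP, which encodes a secreted peptide (-2.61, SE 0.27), also fell.

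The other genes with the largest changes overlap a neighbouring tested gene on either strand in GENCODE v29, so their values are uncertain. The strand used in counting is not given in the sources used here, and it would not settle overlaps on the same strand. Among the genes named by the rule, the largest rise was in GLIPR1, a pathogenesis-related protein gene overlapping KRR1 (4.58, SE 0.18, 1.25 to 29.7 CPM). It was followed by the RNA helicase gene DDX47 overlapping APOLD1 (3.82, SE 0.26, 1.42 to 20.5 CPM) and the translation factor gene EIF4A1 overlapping SENP3-EIF4A1 (3.39, SE 0.38, 12.1 to 126 CPM). SNORA33, within RPS12, rose by 2.94 (SE 0.16), RPL30-AS1, overlapping RPL30, by 2.72 (SE 0.18), and the long non-coding RNA CHASERR, overlapping an unnamed gene, by 2.08 (SE 0.12). The RNA-binding protein genes RBM15 (2.21, SE 0.10; 20.5 to 94.7 CPM) and RBM4 (2.08, SE 0.10; 12.7 to 53.5 CPM) overlap RBM15-AS1 and the paralog RBM4B. The proteasome subunit gene PSMA2 rose by 1.999 (SE 0.21, overlap with MRPL32) and the kinase subunit gene CSNK2B by 1.97 (SE 0.16, overlap with GPANK1). Among falls, PPP1R10, which encodes a regulator of protein phosphatase 1, dropped from 229.9 to 19.4 CPM (-3.56, SE 0.23, overlap with MRPS18B) and MEPCE (ENSG00000146834), which encodes the capping enzyme of 7SK RNA, from 115.4 to 11.1 CPM (-3.38, SE 0.14, overlap with ZCWPW1). C1orf74 (-3.04, SE 0.19; TRAF3IP3) and LENG9 (-2.75, SE 0.21; LENG8) also fell. The highest adjusted p among all these genes was 6.63e-05, for EIF4A1.

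Of genes often followed with CDK9 inhibitors, HEXIM1 (ENSG00000186834), which encodes an inhibitor of the CDK9 complex, fell from 73.9 ± 1.61 to 24.2 ± 0.41 CPM (-1.61, SE 0.10, adjusted p = 1.71e-10, overlap with HEXIM2-AS1). CDK9 (ENSG00000136807), the kinase itself, rose from 55.6 ± 1.09 to 92.0 ± 0.046 CPM (0.73, SE 0.08, adjusted p = 3.66e-07). MYC, a transcription factor gene with a short-lived transcript, stood at 164.8 and 173.5 CPM (0.075, SE 0.08, adjusted p = 0.468). KLK3, which encodes prostate-specific antigen, stood at 1052 and 1110 CPM (0.077, SE 0.11, adjusted p = 0.595). MCL1, which encodes a short-lived survival protein, had a value of 0.41 (SE 0.10, adjusted p = 0.00181) that lost its call when scaled by library size only (0.16, adjusted p = 0.111), and it overlaps ADAMTSL4-AS1.

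In Scr, AT7519 raised 5206 and lowered 5866 of the 23830 tested genes (46.5%), of which 1511 and 2782 changed 2-fold or more. The median of all genes moved by 0.15 with upper-quartile scaling and by -0.25 with library size only. The split moved with it, to 6714 higher and 4730 lower and to 3024 higher and 8207 lower. All changes are therefore relative to the bulk of genes, with no spike-in named in the labels. Differences between same-numbered replicates correlated across siRNA arms within an agent (r 0.604 to 0.734) and not between agents (-0.135 to 0.038). Samples with DMSO and with AT7519 may thus differ in more than the agent, which these changes cannot tell apart. With each library left out in turn the count was 8902 to 11451.

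**Figure D2:**
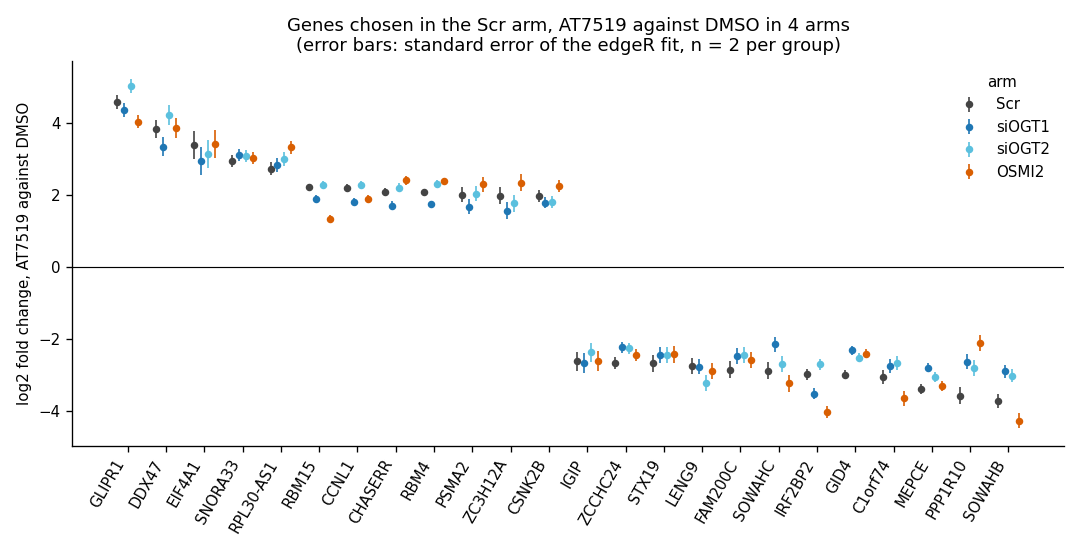
Log2 fold change under AT7519 in each of the 4 arms for genes chosen in Scr, with bars of 1 SE from edgeR (2 libraries per group). Genes overlapping another tested gene on either strand are uncertain, and the counting strand is not given.

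Gene lists fixed before the data were examined grouped these changes, and 12 of 28 lists tested with camera passed in Scr. All 74 cytosolic ribosomal protein genes rose (74 adjusted over the list alone, median 0.77, adjusted p = 1.94e-45, or 0.0711 with an estimated correlation), among them RPS15A (1.39), RPS16 (0.89), RPS15 (0.91) and RPS19 (0.91). All 44 nuclear oxidative phosphorylation genes rose as well (44 adjusted over the list alone, median 0.70, adjusted p = 1.03e-24, or 0.0543 with an estimated correlation), such as COX4I1 (0.83), NDUFV1 (0.78) and NDUFA9 (1.18). Of 20 snoRNA host genes, 17 rose, 0 fell and 3 did not pass (median 0.66, adjusted p = 4.24e-13), with SNHG15 going from 53.6 to 187.9 CPM (1.81) and GAS5 from 283.6 to 690.6 CPM (1.28). Of 491 measured ZNF genes, 54 rose, 276 fell and 161 did not pass (58 and 285 adjusted over the list alone, median -0.58, adjusted p = 5.67e-11), with falls of ZNF397 (-1.48), ZNF253 (-2.26), ZNF623 (-2.27) and ZNF646 (-1.84). The calls of the snoRNA host and ZNF lists held with an estimated correlation (adjusted p = 0.0424 for each) and those of the other 10 lists did not.

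Of 50 core spliceosome genes, 36 rose, 1 fell and 13 did not pass (median 0.39, adjusted p = 1.78e-08, or 0.0754 with an estimated correlation), with DHX15 going from 375.8 to 596.2 CPM (0.67) and SNRNP70 (0.70), SNRPA1 (0.69) and SNRPD2 (0.74) rising by similar amounts. Of 47 SR and hnRNP splicing regulators, 29 rose, 4 fell and 14 did not pass (33 and 4 adjusted over the list alone, median 0.44, adjusted p = 3.85e-07, or 0.0543 with an estimated correlation), including HNRNPDL (279.9 to 558.5 CPM, 0.997), the SR protein kinase gene CLK3 (1.197) and HNRNPH1 (0.89). Of 37 MYC targets, 21 rose, 4 fell and 12 did not pass (median 0.32, adjusted p = 4.75e-04, or 0.548 with an estimated correlation), for example CDK4 (0.74), the chaperonin gene HSPE1 (0.79) and NOP16 (0.84). Of 29 hypoxia and glycolysis genes, 15 rose, 5 fell and 9 did not pass (17 and 6 adjusted over the list alone, median 0.28, adjusted p = 0.00975, or 0.527 with an estimated correlation), with PGAM1 at 0.70, ALDOA at 0.61 and the HIF target EGLN3 at -1.61. That list lost its call with library size only (median 0.026, adjusted p = 0.116).

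Of 30 immediate early genes, 3 rose, 18 fell and 9 did not pass (4 and 18 adjusted over the list alone, median -0.80, adjusted p = 4.75e-04, or 0.0543 with an estimated correlation), with ATF3 going from 41.8 to 15.1 CPM (-1.47), IER2 at -1.90 and IER5 at -2.27. Of 27 genes with an uninterrupted coding sequence, 2 rose, 12 fell and 13 did not pass (2 and 14 adjusted over the list alone, median -0.43, adjusted p = 0.00273, or 0.565 with an estimated correlation). Of 27 apoptosis regulators, 7 rose, 16 fell and 4 did not pass (median -0.69, adjusted p = 0.00105, or 0.138 with an estimated correlation), including BCL2L11 (45.3 to 10.8 CPM, -2.07), BMF (-1.83) and BIK (-1.78), which encode BH3-only proteins, and XIAP (-1.04), an inhibitor of caspases. Of 33 DNA repair genes, 5 rose, 17 fell and 11 did not pass (median -0.36, adjusted p = 0.00169, or 0.280 with an estimated correlation), with BRCA2 going from 40.5 to 17.2 CPM (-1.23) and XRCC2 (-1.45), FANCM (-1.28) and BARD1 (-0.99) falling.

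The other 16 tested lists did not pass in Scr. Higher, lower and not passed were 10, 13 and 9 of 32 P-TEFb and elongation genes (median -0.008, 0.15 with upper-quartile scaling), 3, 9 and 8 of 20 cleavage and polyadenylation genes (median -0.15; RBBP6 -1.55), 7, 11 and 18 of 36 androgen receptor targets (median -0.09, 0.06 with upper-quartile scaling; C1orf116 -2.52, from 212.1 to 36.9 CPM), and 8, 11 and 14 of 33 G1/S genes. The G1/S list had a median of 0.08 (-0.165 with library size only), a mean of -0.15 and a test direction of down (adjusted p = 0.498), with CCND1 going from 224.1 to 109.4 CPM (-1.04) and CCNE2 at -1.50. They were 6, 10 and 15 of 31 G2/M genes (AURKA -1.60), 7, 14 and 9 of 30 p53 targets (median -0.17; SESN1 -0.82, XPC -1.05, AEN 0.89), 10, 13 and 10 of 33 ATF4 and unfolded protein response genes (median -0.14, 0.01 with upper-quartile scaling; CHAC1 -2.56, HYOU1 0.69) and 13, 5 and 7 of 25 heat shock genes (median 0.34, mean -0.11; DNAJB1 -1.59, HSP90AB1 0.57). They were 10, 4 and 11 of 25 cholesterol genes (median 0.13, -0.11 with library size only; EBP 0.53), 8, 4 and 19 of 31 interferon-stimulated genes (ISG15 0.59), 7, 0 and 12 of 19 replication histones, 2, 1 and 6 of 9 hexosamine genes, 4, 0 and 7 of 11 stromal markers, 0, 0 and 9 of 9 basal markers, 0, 0 and 5 of 5 neuroendocrine markers and 0, 1 and 3 of 4 leukocyte markers. The 13 mitochondrially encoded protein genes were listed at 0 in all samples.

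**Figure D3:**
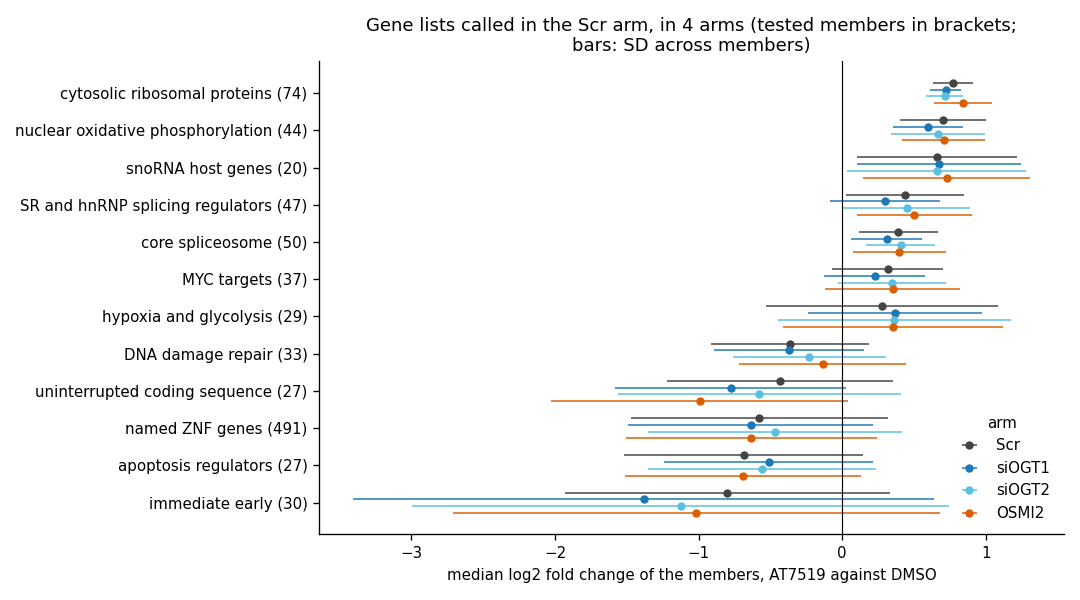
Median log2 fold change under AT7519 in each arm for the 12 lists that passed in Scr, with bars of 1 SD across members and the number of tested members in brackets. These medians kept their sign in Scr under each scaling tried.

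Protein-coding genes with a single exon in every GENCODE v29 transcript (297) had a median of -0.41 under AT7519 in Scr, and those with several exons (14279) a median of -0.07. Lowered shares were 37.7% and 30.1%. The medians were -0.45 and -0.05 in siOGT1, -0.45 and -0.04 in siOGT2, and -0.51 and -0.03 in OSMI2, and at a mean log2 CPM of 3 or more they were -0.29 (104 genes) and 0.03 (9482 genes) in Scr. Across genes in Scr, the fold change correlated with exon number at a Spearman rho of 0.023, with exonic length at -0.162 and with gene span at -0.160 (-0.077, -0.298 and -0.307 at a mean log2 CPM of 3 or more). Per sample, the median log2 CPM of single-exon genes minus that of several-exon genes was -3.67 ± 0.12 with AT7519 and -3.34 ± 0.10 with DMSO (SD, 8 and 8 samples, two-sided exact permutation p = 3.11e-04 over 12870 permutations), and the samples of different arms were treated as exchangeable. The permutation also took all samples as independent, though differences between same-numbered replicates correlated across the siRNA arms of an agent (r 0.604 to 0.734). Its p-value may therefore be too small. By gene type in Scr, 248 of 639 small RNA genes rose and 24 fell (median 1.46), 671 of 2921 pseudogenes rose and 274 fell (0.28), and 667 of 4838 long non-coding genes rose and 1010 fell (-0.25).

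The AT7519 response had the same direction for most changed genes in all 4 arms. AT7519 raised 4634 and lowered 5246 genes in siOGT1, raised 5283 and lowered 5445 in siOGT2, and raised 5624 and lowered 5612 in OSMI2. These splits were 59.1%, 57.8% and 62.1% higher with upper-quartile scaling and 25.5%, 26.1% and 29.2% higher with library size only, against 46.9%, 49.2% and 50.1%. In all 4 arms 3581 genes rose and 3653 fell, where independent lists of these sizes would share 52.97 and 69.49. Differences between same-numbered replicates correlated across the siRNA arms of an agent (r 0.604 to 0.734). The siRNA arms are therefore not independent repeats of the AT7519 response. Scr shared 8515 changed genes of one direction with siOGT1 (3 opposite), 9009 with siOGT2 (0 opposite) and 8963 with OSMI2 (18 opposite). Fold changes correlated across 10158 genes with r of 0.914 to 0.968 between arms, and genes are not independent replicates.

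CCNL1 rose by 1.81 in siOGT1, 2.27 in siOGT2 and 1.88 in OSMI2, GLIPR1 by 4.35, 5.01 and 4.03, RBM15 by 1.88, 2.28 and 1.34, and ZC3H12A by 1.56, 1.76 and 2.34. In the same arms MEPCE fell (-2.78, -3.06 and -3.31), as did SOWAHB (-2.89, -3.01 and -4.25), PPP1R10 (-2.62, -2.81 and -2.10), IRF2BP2 (-3.503, -2.69 and -4.005) and HEXIM1 (-1.18, -1.66 and -1.47). CDK9 had values of 0.33, 0.60 and 0.28 (adjusted p = 0.00256, 4.70e-06 and 0.00629), of which those in siOGT1 and OSMI2 lost their calls with library size only (0.101 and 0.036, adjusted p = 0.333 and 0.749). MYC had values of -0.16 (adjusted p = 0.112), -0.27 (adjusted p = 0.00919) and -0.46 (adjusted p = 6.78e-05). OGT itself fell further in siOGT1 (-0.70, adjusted p = 5.35e-04, or -0.41 and 0.0236 without siOGT1 replicate 1 under DMSO). The 74 ribosomal protein genes and the 44 oxidative phosphorylation genes all rose in each arm, with medians of 0.72, 0.715 and 0.84, and of 0.60, 0.67 and 0.71. Immediate early genes fell in 19, 21 and 21 of 30 (medians -1.38, -1.12 and -1.02, or -1.22, -0.915 and -0.92 with members at 0 in a group set highest), and ZNF genes in 299, 250 and 290 of 491. The lists that passed numbered 15, 11 and 17, of which 3, 5 and 7 held with an estimated correlation.

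Knockdown of OGT without AT7519 changed a set of genes with both siRNAs. MAP4K1 (ENSG00000104814), which encodes a kinase of the JNK pathway, rose from 3.37 CPM in Scr to 15.2 with siOGT1 (log2 fold change 2.17, SE 0.17) and 12.4 with siOGT2 (1.88, SE 0.17). FBXO15 (ENSG00000141665), an F-box protein gene, rose from 5.10 to 22.1 (2.11, SE 0.15) and 14.9 CPM (1.55, SE 0.15). PTPRJ (ENSG00000149177), which encodes a receptor tyrosine phosphatase, fell from 57.1 to 28.8 (-0.99, SE 0.11) and 29.5 CPM (-0.95, SE 0.11). GRIN3A, an NMDA receptor subunit gene, fell from 13.9 to 6.41 (-1.12, SE 0.17) and 5.67 CPM (-1.29, SE 0.17). SNHG3, a snoRNA host gene that overlaps RCC1, fell from 111.5 to 62.1 (-0.84, SE 0.09) and 60.3 CPM (-0.89, SE 0.09). Further rises with siOGT1 and siOGT2 were those of the ankyrin gene ANKRD24 (1.46, 1.09), the serpin gene SERPINI1 (1.29, 0.99) and the synaptic gene PCLO (0.96, 1.02). Uncertain because of an overlapping gene were the rises of APOLD1 (1.60, 1.63; DDX47), C9orf43 (1.52, 1.29; POLE3), ARHGAP4 (1.18, 1.01; NAA10), PRKAR1B (1.23, 0.99; DNAAF5) and CCT6B (1.29, 0.94; LIG3). Further falls were those of RIPOR2 (-0.95, -1.18, overlap with PPIAP29), RFLNB (-0.88, -0.995), FRMPD2 (-0.88, -0.98), the claudin gene CLDN8 (-0.87, -0.94) and the CaMKII inhibitor gene CAMK2N1 (-0.85, -1.83).

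Some of these calls rested on single libraries. CLDN8 was not called with siOGT1 without Scr replicate 1 (adjusted p = 0.0803) or siOGT1 replicate 2 (0.103), and with siOGT2 without Scr replicate 1 (0.105), Scr replicate 2 (0.0508) or siOGT2 replicate 2 (0.1799). CAMK2N1 was not called with siOGT1 without Scr replicate 1 (0.0922) or siOGT1 replicate 2 (0.118), and PCLO (0.0646) and FRMPD2 (0.0763) were not called with siOGT2 without siOGT2 replicate 2, all under DMSO. Among genes with the largest changes by 1 siRNA, MAP2K4, which encodes a JNK-pathway kinase, went from 68.4 to 15.2 CPM with siOGT1 (-2.17, adjusted p = 1.54e-09), the secreted protein gene AGR2 from 21.02 to 4.67 CPM (-2.16, adjusted p = 2.01e-04) and the histone variant gene MACROH2A1 from 274 to 101.8 CPM (-1.43, adjusted p = 7.24e-10, overlap with PITX1-AS1). With siOGT2, UGT2B11, a glucuronosyltransferase gene with close paralogs, had a value of 1.199 (adjusted p = 0.00360) and the protease gene CTSL fell (-1.28, adjusted p = 2.83e-04).

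siOGT1 raised 1165 and lowered 1314 genes (262 and 180 by 2-fold or more), and siOGT2 raised 457 and lowered 568 (106 and 52). These counts treat replicates as independent. With a replicate block within agent and kind of arm, chosen after the data were seen, they were 6560 for siOGT1, 4597 for siOGT2 and 3152 shared in direction. The higher share for siOGT1 was 60.2% with library size only against 47.0%, and for siOGT2 it was 55.1% with upper-quartile scaling and 62.5% with library size only against 44.6%. The siOGT1 count was 1084 without Scr replicate 1, 1042 without Scr replicate 2, 1364 without siOGT1 replicate 1 and 790 without siOGT1 replicate 2, all under DMSO. The siOGT2 count was 301 without Scr replicate 1, 247 without Scr replicate 2, 389 without siOGT2 replicate 1 and 184 without siOGT2 replicate 2. Both siRNAs raised 347 and lowered 325 genes (672), where independent lists would share 53.66, and 4 genes were opposite. That shared count was 195 and 171 without either Scr library, 415 and 342 without either siOGT1 library, and 277 and 142 without either siOGT2 library.

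Both siRNAs were compared with the same 2 Scr libraries, which cannot be split into 2 sets of 2, so part of the excess may come from the shared controls. Across 10158 genes, which are not independent replicates, the fold changes correlated with r = 0.704, and 20 simulated pairs of unchanged groups against the same controls gave 0.499 (0.482 to 0.523), drawn with independent replicates. The covariance was 0.0439 and the simulated one 0.0082, a difference of 0.0356 that estimates the shared effect only if replicates are independent.

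**Figure D4:**
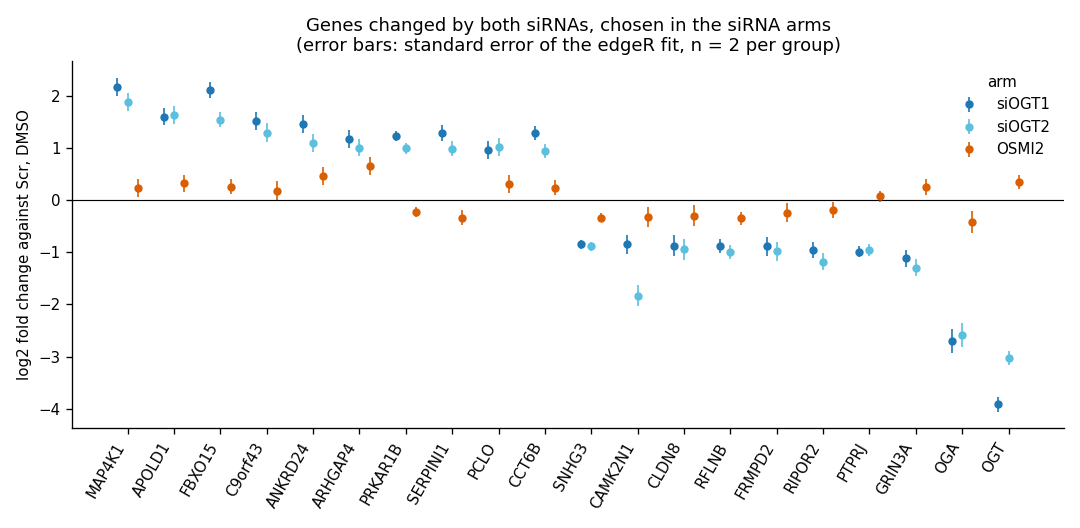
Log2 fold change against Scr under DMSO of the genes named for both siRNAs, for siOGT1, siOGT2 and OSMI2, with bars of 1 SE from edgeR (2 libraries per group). All comparisons use the same Scr libraries.

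With siOGT1, 14 of 28 lists passed and 3 held with an estimated correlation. The 9 hexosamine genes included 4 that fell and 5 that did not pass (median -0.38, adjusted p = 5.48e-16, or 5.94e-04 with an estimated correlation), among them OGT, OGA and GFPT1, which encodes the entry enzyme of the pathway (161.4 to 93.4 CPM, -0.79). This hexosamine and O-GlcNAc list holds the siRNA target, and in runs chosen after the data were seen its adjusted p was 1.35e-05 without OGT (0.0361 with an estimated correlation) and 0.0123 without OGT and OGA (0.0912). Of 47 SR and hnRNP regulators, 20 fell and 27 did not pass (23 adjusted over the list alone, median -0.22, adjusted p = 1.13e-10, or 0.0362 with an estimated correlation), with HNRNPA1 going from 2176 to 1450 CPM (-0.59), HNRNPDL at -0.55 and RBM39 at -0.49. Of 491 ZNF genes, 6 rose, 83 fell and 402 did not pass (6 and 104 adjusted over the list alone, median -0.18, adjusted p = 7.60e-08, or 0.0390 with an estimated correlation), with ZNF143, a transcription factor of snRNA genes, rising from 38.7 to 83.4 CPM (1.11) and ZNF772 (-0.89) and ZNF791 (-0.71) falling. Of 33 G1/S genes, 1 rose, 9 fell and 23 did not pass (1 and 15 adjusted over the list alone, median -0.22, adjusted p = 3.43e-05, or 0.492 with an estimated correlation), including CCNE1 (-0.71), RRM2 (-0.65) and CDC6 (-0.56). Of 33 ATF4 and unfolded protein response genes, 9 fell and 24 did not pass (13 adjusted over the list alone, median -0.27, adjusted p = 3.44e-07, or 0.289 with an estimated correlation), such as HERPUD1 (-0.95) and the cystine transporter gene SLC7A11 (-0.85).

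Of 20 snoRNA host genes, 7 fell with siOGT1 and 13 did not pass (11 adjusted over the list alone, median -0.28, adjusted p = 2.16e-07, or 0.0866 with an estimated correlation), with SNHG9 at -0.67 and SNHG1 at -0.65. Of 31 interferon-stimulated genes, 7 fell and 24 did not pass (1 and 12 adjusted over the list alone, median -0.345, adjusted p = 7.53e-05, or 0.0866 with an estimated correlation), including IFIT2 (-1.39), IFI44 (-0.92) and ISG20 (-0.75). Of 74 ribosomal protein genes, 12 fell and 62 did not pass (13 adjusted over the list alone, median -0.14, adjusted p = 3.44e-07, or 0.492 with an estimated correlation). Of 30 p53 targets, 5 fell and 25 did not pass (6 adjusted over the list alone, median -0.14, adjusted p = 0.00131, or 0.0991 with an estimated correlation), with PMAIP1 at -1.003. Of 30 immediate early genes, 1 rose, 8 fell and 21 did not pass (median -0.29, adjusted p = 0.00489, or 0.0912 with an estimated correlation), with ATF3 at -0.70. The cholesterol list (6 higher, 1 lower, 18 not passed; median 0.16, adjusted p = 0.0215, or 0.525 with an estimated correlation) lost its call without siOGT1 replicate 1 (0.239) or Scr replicate 2 (0.284). In it MVD, which encodes an enzyme of the mevalonate pathway, went from 37.9 to 58.2 CPM (0.62) and the lanosterol synthase gene LSS rose by 0.61. The core spliceosome, replication histones, and cleavage and polyadenylation lists passed with all libraries and not without siOGT1 replicate 1 (adjusted p = 0.0728, 0.303 and 0.0728) or Scr replicate 2 (0.134, 0.222 and 0.0728). With an estimated correlation they were not called either (0.492, 0.4998 and 0.349), and the core spliceosome and cleavage lists also lost their calls with upper-quartile scaling and library size only.

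With siOGT2, 17 of 28 lists passed and 3 held with an estimated correlation. Of 9 hexosamine genes, 3 fell and 6 did not pass (median -0.21, adjusted p = 7.58e-11, or 0.00314 with an estimated correlation). In the same runs the hexosamine and O-GlcNAc list had an adjusted p of 0.00835 without OGT (0.109 with an estimated correlation) and 0.678 without OGT and OGA (0.684), so its call rested on these 2 genes. Of 47 SR and hnRNP regulators, 12 fell and 35 did not pass (28 adjusted over the list alone, median -0.24, adjusted p = 3.26e-12, or 0.0240 with an estimated correlation), with HNRNPA1 at -0.43. Of 20 snoRNA host genes, 6 fell and 14 did not pass (9 adjusted over the list alone, median -0.25, adjusted p = 6.85e-11, or 0.0483 with an estimated correlation). Of 33 G1/S genes, 18 fell and 15 did not pass (26 adjusted over the list alone, median -0.41, adjusted p = 3.49e-21, or 0.121 with an estimated correlation), with RRM2 (-0.65), the helicase subunit gene MCM7 (-0.51) and UNG (-0.51), whose calls were lost without siOGT2 replicate 2 (adjusted p = 0.0542, 0.0746 and 0.0820). Of 31 G2/M genes, 7 fell and 24 did not pass (17 adjusted over the list alone, median -0.29, adjusted p = 5.99e-12, or 0.185 with an estimated correlation).

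Of 25 cholesterol genes, 7 rose with siOGT2, 1 fell and 17 did not pass (12 and 1 adjusted over the list alone, median 0.21, adjusted p = 6.06e-10, or 0.173 with an estimated correlation), with MVD at 67.4 CPM (0.83), LSS at 0.83 and EBP at -0.67. Of 74 ribosomal protein genes, 10 fell and 64 did not pass (19 adjusted over the list alone, median -0.16, adjusted p = 2.15e-11, or 0.3501 with an estimated correlation). Of 50 core spliceosome genes, 7 fell and 43 did not pass (8 adjusted over the list alone, median -0.13, adjusted p = 8.89e-07, or 0.137 with an estimated correlation). Of 491 ZNF genes, 1 rose, 23 fell and 467 did not pass (2 and 31 adjusted over the list alone, median -0.13, adjusted p = 2.00e-05, or 0.109 with an estimated correlation), with ZNF143 at 0.81 and ZNF567 at -0.62. The cleavage (median -0.17), DNA repair (-0.13) and ATF4 (-0.18) lists also passed (adjusted p = 3.45e-04, 0.00115 and 0.00163, or 0.109, 0.203 and 0.3501 with an estimated correlation). Not every list that passed with siOGT2 is described here. MYC targets had a median of -0.125 with siOGT2.

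Under DMSO, 117 genes were higher and 593 lower in the OSMI2 arm than in Scr, and few of them changed 2-fold (24 and 8). Whether OSMI2 cells got scrambled siRNA is not given, so a difference in transfection or handling may be part of these changes. MVD (ENSG00000167508) rose from 37.9 ± 2.20 to 74.2 ± 10.3 CPM (0.97, SE 0.10, adjusted p = 8.52e-05) and MSMO1, a sterol oxidase gene, from 124.5 to 220.2 CPM (0.82, adjusted p = 6.99e-04). NCAPH, which encodes a condensin subunit, fell from 74.4 ± 0.26 to 44.8 ± 2.59 CPM (-0.73, SE 0.09, adjusted p = 8.81e-04). The tubulin gene TUBA4A (-0.79, SE 0.07, adjusted p = 1.70e-05, overlap with STK16) fell and the endoplasmic reticulum chaperone gene DNAJB9 (0.99, SE 0.16, adjusted p = 0.00252, overlap with PNPLA8) rose. These 5 genes were called with each library left out in turn. The remaining genes of the largest changes were RUSC1-AS1 (1.13, overlap with FDPS), BEST1 (1.03, overlap with FTH1), NIBAN1 (0.997), UGT2B10 (-1.03), LINC00161 (-0.78) and the peptide gene APLN (-0.70). Without Scr replicate 2 under DMSO their adjusted p-values were 0.353, 0.106, 0.385, 0.108, 0.450 and 0.288, and without OSMI2 replicate 1 under DMSO they were 0.0569, 0.0622, 0.248, 0.0766, 0.227 and 0.155. UGT2B10 (0.0877), APLN (0.0776), RUSC1-AS1 (0.274) and LINC00161 (0.0562) were not called without OSMI2 replicate 2 either, nor RUSC1-AS1 (0.0989) and NIBAN1 (0.123) without Scr replicate 1. NIBAN1 was also not called without siOGT2 replicate 1 (0.0564) or 2 (0.0565) under DMSO, or Scr replicate 1 (0.0578) or 2 (0.0571) with AT7519.

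The OSMI2 count of 710 was 356 without Scr replicate 1, 9 without Scr replicate 2, 168 without OSMI2 replicate 1 and 36 without OSMI2 replicate 2, all under DMSO. It was 378 with upper-quartile scaling (157 higher, 221 lower) and 390 with library size only (209 higher, 181 lower), which moved the median of all genes by 0.10. OSMI2 shared 115 called genes of one direction with siOGT1 (38.42 for independent lists, 42 opposite) and 121 with siOGT2 (16.38, 7 opposite). The fold changes of OSMI2 and siOGT1 correlated across genes with r = 0.067 against 0.499 simulated for unchanged groups with the same Scr libraries (covariance difference -0.0045), and those of OSMI2 and siOGT2 with r = 0.284 against 0.495 (covariance difference 0.0041). All 3 arms shared 23 genes higher and 50 lower than Scr (0.110 and 0.779 for independent lists), and part of that excess may come from the shared controls.

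Of 28 lists, 15 passed for OSMI2 against Scr and 3 held with an estimated correlation. Of 37 MYC targets, 24 fell and 13 did not pass (32 adjusted over the list alone, median -0.39, adjusted p = 1.64e-33, or 0.0305 with an estimated correlation). Of 50 core spliceosome genes, 12 fell and 38 did not pass (31 adjusted over the list alone, median -0.24, adjusted p = 7.26e-19, or 0.0305 with an estimated correlation), with SNRPF at -0.54. Of 47 SR and hnRNP regulators, 12 fell and 35 did not pass (21 adjusted over the list alone, median -0.20, adjusted p = 1.29e-10, or 0.0305 with an estimated correlation), with HNRNPA2B1 going from 2386 to 1609 CPM (-0.57). The calls of SNRPF and HNRNPA2B1 were lost without Scr replicate 2 (adjusted p = 0.0727 for each). Of 33 G1/S genes, 17 fell and 16 did not pass (31 adjusted over the list alone, median -0.41, adjusted p = 1.01e-30, or 0.0703 with an estimated correlation). Of 31 G2/M genes, 9 fell and 22 did not pass (17 adjusted over the list alone, median -0.29, adjusted p = 8.62e-14, or 0.148 with an estimated correlation). NCL, a MYC target, had a value of -0.55 and MCM6, a G1/S gene, of -0.55, and both lost their calls without Scr replicate 2 (adjusted p = 0.0795 and 0.0727) or OSMI2 replicate 2 (0.0545 and 0.0691).

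Of 25 cholesterol genes, 7 rose in OSMI2, 1 fell and 17 did not pass (14 and 3 adjusted over the list alone, median 0.30, adjusted p = 3.38e-14, or 0.103 with an estimated correlation). Of 25 heat shock genes, 9 fell and 16 did not pass (14 adjusted over the list alone, median -0.35, adjusted p = 1.99e-13, or 0.0703 with an estimated correlation). Of 44 oxidative phosphorylation genes, 7 fell and 37 did not pass (15 adjusted over the list alone, median -0.17, adjusted p = 2.30e-11, or 0.145 with an estimated correlation). Of 33 ATF4 and unfolded protein response genes, 3 rose and 30 did not pass (4 adjusted over the list alone, median 0.21, adjusted p = 1.63e-07, or 0.174 with an estimated correlation). The ribosomal (-0.15), DNA repair (-0.14), snoRNA host (-0.25), hypoxia (-0.14) and cleavage (-0.135) lists had lower medians (adjusted p = 8.23e-10, 1.14e-05, 1.14e-05, 5.55e-05 and 0.00168, or 0.400, 0.107, 0.107, 0.151 and 0.107 with an estimated correlation). The P-TEFb list (-0.13, adjusted p = 0.00393, or 0.194 with an estimated correlation) was not called with library size only (-0.031, adjusted p = 0.113).

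Whether OGT loss altered the AT7519 response was tested as an interaction. Here a higher or lower response is a more positive or more negative AT7519 log2 fold change than in Scr. A lower response can therefore be a stronger fall, and a higher response a weaker fall. With siOGT1, 12 of 23830 genes differed from Scr, 9 with a higher and 3 with a lower response. GDPD1, a phosphodiesterase gene, had a higher response (1.33, SE 0.15, adjusted p = 6.65e-04; 28.2 to 13.8 CPM in siOGT1) as had DENND6A, a trafficking gene (1.025, SE 0.135, adjusted p = 0.00233). GCH1, which encodes GTP cyclohydrolase, had a lower response (-1.135, SE 0.15, adjusted p = 0.00233). PUDP (1.203) lost its call without siOGT1 replicate 1 under DMSO (adjusted p = 0.0636) or Scr replicate 2 with AT7519 (0.0509). The count was 4 without Scr replicate 1 and 5 without Scr replicate 2 under DMSO, 3 and 5 without siOGT1 replicates 1 and 2 under DMSO, 4 without Scr replicate 2 and 5 without siOGT1 replicate 2 with AT7519, and 22 without siOGT2 replicate 1 or 2 with AT7519. With siOGT2, 0 genes passed in edgeR (928 at an unadjusted p under 0.05, lowest adjusted p = 0.620), and DESeq2 called 3, limma voom 0 and limma on the normalized values 0. A replicate block within agent and kind of arm, chosen after the data were seen, called 254 genes for siOGT2 and 949 for siOGT1, so these counts depend on whether same-numbered samples are treated as paired. The count was 2 without siOGT2 replicate 1 with AT7519. The list of immediate early genes had a lower response in siOGT1 (median -0.36, adjusted p = 4.81e-05, or 0.0578 with an estimated correlation; 0 of 30 members passed) and the DNA repair list a higher one in siOGT2 (median 0.13, adjusted p = 0.00372, or 0.777 with an estimated correlation; 0 of 33 members passed).

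In OSMI2, 178 genes responded to AT7519 differently from Scr, 20 with a higher and 158 with a lower response. PPM1D (ENSG00000170836), a phosphatase gene of the p53 pathway, had a lower response (-1.39, SE 0.16, adjusted p = 5.05e-04) and stood at 27.3 ± 1.93 CPM under DMSO and 7.13 ± 0.48 CPM with AT7519 in OSMI2 (overlap with RNU6-623P). VASN, a TGF-beta-binding protein gene that overlaps CORO7, had a lower response too (-1.67, SE 0.235, adjusted p = 0.00256). CCN1, a matricellular immediate early gene, had a lower response as well (-2.38, adjusted p = 0.00106), and SMAD6, an inhibitory SMAD gene, a higher one (1.62, SE 0.25, adjusted p = 0.00311). These 4 genes were called with each library left out in turn. The count was 35 and 37 without Scr replicates 1 and 2, 50 and 28 without OSMI2 replicates 1 and 2, and 118 without siOGT2 replicate 1 or 2, all under DMSO. With AT7519 it was 57 and 341 without Scr replicates 1 and 2, 309 without siOGT1 replicate 1 or 2, 329 without siOGT2 replicate 1 or 2, and 371 and 59 without OSMI2 replicates 1 and 2.

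Of 28 lists, 11 differed in response between OSMI2 and Scr and 3 held with an estimated correlation. Of 25 cholesterol genes, 10 had a lower response and 15 did not pass (19 adjusted over the list alone, median -0.59, adjusted p = 1.08e-36, or 0.0150 with an estimated correlation). Of 30 p53 targets, 4 had a lower response and 26 did not pass (12 adjusted over the list alone, median -0.26, adjusted p = 9.21e-14, or 0.00450 with an estimated correlation). Of 30 immediate early genes, 6 had a lower response and 24 did not pass (9 adjusted over the list alone, median -0.49, adjusted p = 7.74e-10, or 0.00450 with an estimated correlation). Genes with an uninterrupted coding sequence (2 lower, 25 not passed; 9 adjusted over the list alone, median -0.425, adjusted p = 1.18e-10) did not hold with an estimated correlation (0.210). No difference in the response of the cholesterol list passed between siOGT1 and Scr (median 0.04, adjusted p = 0.661) or between siOGT2 and Scr (median 0.05, adjusted p = 0.886). Relative to Scr its median in OSMI2 was 0.30 under DMSO and -0.30 with AT7519 (bootstrap 95% interval over genes -0.38 to -0.16), where 0 members were higher and 11 lower. INSIG1, a sterol sensor gene, went from 0.88 to -0.37 and MVD from 0.97 to 0.19 by the same measure, and neither passed with AT7519 (adjusted p = 0.467 and 0.256).

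**Figure D5:**
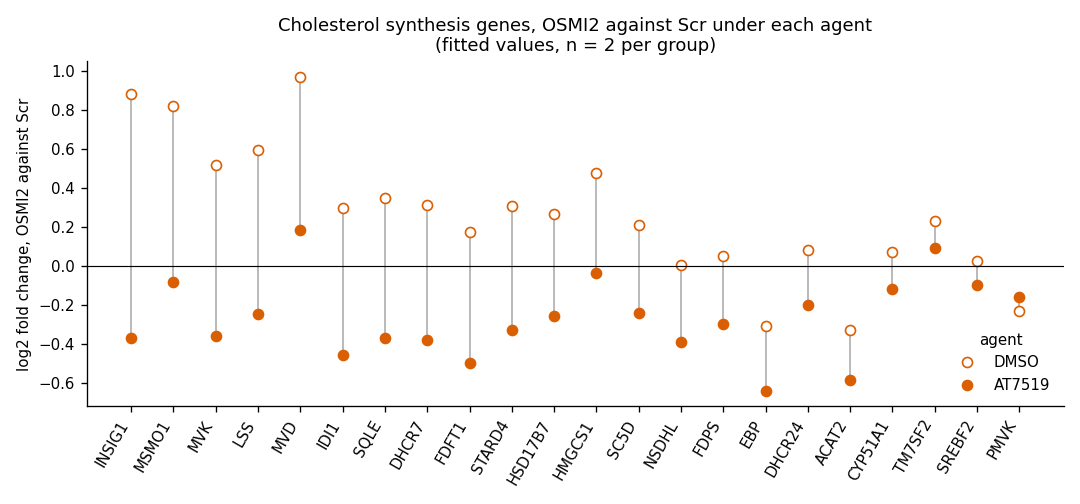
Log2 fold change of cholesterol genes in OSMI2 against Scr under DMSO and with AT7519, 1 point per gene and agent from 2 libraries per group. Not all members of the list are shown.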

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

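For the results below the AT7519 response of an arm differed from that of Scr by the interaction test, and the comparison of ribosomal with oxidative phosphorylation medians and both tests of the cholesterol pattern were chosen only after the result was seen. With siOGT1, 12 genes differed, among them GCH1 (-1.135), SLC26A2 (-1.011), ZNF217 (-0.602), IL1R1 (0.949), DENND6A (1.025), GPR157 (1.064), PUDP (1.203) and GDPD1 (1.332). SLC26A2 was not called without 6 of the libraries in turn (adjusted p = 0.0506 to 0.162), ZNF217 without 13 (0.052 to 0.348), GPR157 without 4 (0.0636 to 0.11) and IL1R1 without 6 (0.0506 to 0.146), and the highest values came without siOGT1 replicate 1 under DMSO for SLC26A2 and ZNF217, Scr replicate 2 with AT7519 for GPR157 and siOGT1 replicate 2 under DMSO for IL1R1. The lists that differed with siOGT1 were immediate early genes (median -0.363), uninterrupted coding sequence (-0.188), SR and hnRNP regulators (-0.082), MYC targets (-0.055), snoRNA hosts (-0.172), ribosomal proteins (-0.053), oxidative phosphorylation (-0.065) and ZNF genes (-0.072). Of these 8 lists 0 were called with an estimated correlation, and the ribosomal list also lost its call with library size only. With siOGT2 the lists were immediate early genes (-0.106), DNA repair (0.132), interferon-stimulated genes (-0.125) and ribosomal proteins (-0.057), and 0 of these 4 lists were called with an estimated correlation. The ribosomal median turned to 0.015 in siOGT1 without siOGT1 replicate 2, and to 0.032 in siOGT2 without siOGT2 replicate 2, both with AT7519.

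With OSMI2, 178 genes differed, among them BTG2 (-1.803), VASN (-1.667), PPM1D (-1.391), CLP1 (-1.384), IRF2BP2 (-1.034), RBM15 (-0.863), MYC (-0.539), ZNF75A (0.846), ZNF382 (1.010), GVQW3 (1.022), PPP1R10 (1.464) and SMAD6 (1.621). BTG2 was not called without 12 of the libraries in turn (adjusted p = 0.0628 to 0.188), CLP1 without 8 (0.0538 to 0.168), PPP1R10 without 10 (0.0846 to 0.186), GVQW3 without 10 (0.0508 to 0.205), ZNF382 without 11 (0.0582 to 0.312), MYC without 6 (0.0528 to 0.182) and ZNF75A without 4 (0.066 to 0.0801). The highest values came without Scr replicate 1 under DMSO for CLP1, GVQW3, MYC and ZNF75A, Scr replicate 2 under DMSO for BTG2, OSMI2 replicate 2 under DMSO for PPP1R10 and OSMI2 replicate 2 with AT7519 for ZNF382. The lists that differed were P-TEFb (-0.057), immediate early genes (-0.486), uninterrupted coding sequence (-0.425), androgen receptor targets (-0.052), G2/M (-0.103), p53 targets (-0.260), apoptosis regulators (-0.051), ATF4 (-0.106), cholesterol (-0.591), ribosomal proteins (0.072) and ZNF genes (-0.068). Among them, only the immediate early, p53 and cholesterol lists were called with an estimated correlation, and the ribosomal list lost its call with RLE scaling.

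Cholesterol genes had a lower response to AT7519 in OSMI2 than in Scr (median difference -0.591, or -0.689 to -0.492 with each library left out). Chance high values of the OSMI2 libraries under DMSO could give such a difference. OSMI2 was above Scr under DMSO (median 0.297, or 0.339 and 0.204 without OSMI2 replicates 1 and 2, and 0.380 and 0.186 without Scr replicates 1 and 2) and below it with AT7519 (-0.300, bootstrap over genes -0.382 to -0.161). Measured between libraries, the latter difference was -0.349, with a 95% interval of -0.597 to -0.101 from the spread in all 8 groups and of -0.839 to 0.141 from the 2 groups compared. If chance high values were the cause, the true difference with AT7519 would be near 0. The range set for this, after the result was seen, was -0.1 to 0.1. Both intervals are wider than that range, and the first treats replicates as independent, so this explanation stays open. A difference in handling between OSMI2 and siRNA samples may also give it. Replicate deviations of the 2 kinds of sample did not go together (highest r 0.185 of 12 pairs). Those of siRNA samples with DMSO and with AT7519 did not go together either (r -0.135 to 0.038), so the low r does not single out OSMI2. An effect of OSMI2 besides OGT loss is possible as well, as no difference in the response of this list passed for either siRNA, and the data here leave these open.

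Genes that rose 2-fold or more in Scr were enriched among genes that overlap or closely follow another tested gene on the same strand (odds ratio 2.324, interval 2.083 to 2.594, with 686 of 6970 against 734 of 16362). The overlaps named for single genes above were taken on either strand, so such a gene need not belong to that class. Gene types were not separated in this comparison, and they differed in Scr. Called higher were 38.8% of small RNA genes and 23.5% of protein-coding genes. Reads of an overlapping or upstream gene, for instance from transcription past its end, could be counted to the gene that follows. At a mean log2 CPM of 3 or more the odds ratio was 1.903 with a lower bound of 1.207 (37 of 2848 against 50 of 7280 genes). That mean is taken over all 16 samples, so genes with low counts under DMSO can pass it through their AT7519 samples, as GLIPR1 and DDX47 did. The filter therefore cannot judge low counts under DMSO as a cause of the enrichment. Most of the 2-fold rises lay in genes below that mean. Gene counts cannot tell whether such reads come from neighbours, so the rises of GLIPR1 and DDX47 stay open.

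Ribosomal protein and oxidative phosphorylation genes rose together in all arms, as scaling to a fixed total could produce if most other transcripts fell. Measured between libraries, the difference of the list medians changed most in OSMI2 (0.117, with a 95% interval of 0.023 to 0.212 from the spread in all 8 groups and of -0.022 to 0.257 from the 2 groups compared). The intervals of the other arms included 0 and reached past 0.1, and there is no spike-in, so a common shift stays open. Fold change in Scr was nearly unrelated to mean log2 CPM across genes (Spearman rho 0.084). A preference of the test for abundant genes would act on calls and not on fold changes, so this correlation cannot judge it.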

How the results depend on the processing

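The replicate block within agent and kind of arm, the blocks on the 4 libraries of siOGT2, and the hexosamine list without OGT or OGA, were chosen after the data were seen. For named genes 18261 of 19561 alternative values kept their side of the threshold, 855 lost and 445 gained a call and 0 reversed. For lists 7239 of 7650 kept their side, 247 lost, 161 gained and 3 reversed. A change of direction counted as reversed only where either value was called, so values called in neither setting could change direction and count as kept. Reversed medians were those of ribosomal proteins in the siOGT1 interaction without siOGT1 replicate 2 with AT7519 (0.015, from -0.132 over the libraries left out) and in the siOGT2 interaction without siOGT2 replicate 2 with AT7519 (0.032, from -0.176), and of G1/S genes in the OSMI2 interaction without OSMI2 replicate 2 under DMSO (-0.074, up to 0.205), all with fewer samples. A minimum fold of 2 left 4293, 3505, 4059 and 4468 genes for AT7519 in Scr, siOGT1, siOGT2 and OSMI2, 442, 158 and 32 for siOGT1, siOGT2 and OSMI2 against Scr, 6 and 57 for the siOGT1 and OSMI2 interactions, and 104 for both siRNAs. Testing only genes with a mean log2 CPM of 3 or more gave 6806, 6339, 6544 and 7151 for AT7519, with fewer genes tested. Without a low-count filter the interactions gave 100, 8 and 551. Upper-quartile scaling gave 378 for OSMI2 against Scr, and library size only gave 390 and, for the siOGT1 interaction, 20. A fit of the compared groups only gave 4007, 1805 and 1684 against Scr, 287 for the OSMI2 interaction and 1271 for both siRNAs. DESeq2 gave 1586 for siOGT2 and 1420 for OSMI2 against Scr, 118, 3 and 478 for interactions and 1066 for both siRNAs, and limma voom 28 for the siOGT1 interaction. Apart from construction, the cause was not tested. With each library left out the counts were 8902 to 11451, 7497 to 10305, 8521 to 10966 and 8997 to 11472 for AT7519, 790 to 2868, 184 to 1247 and 9 to 751 against Scr, 3 to 22, 0 to 2 and 28 to 371 for interactions, and 142 to 832 for both siRNAs, where the lone sample left was assumed to vary like other groups. Deviations of same-numbered samples correlated at 0.604 to 0.734 within siRNA samples of an agent, 0.432 within OSMI2 and -0.135 to 0.185 between these sets. Samples of a set thus shared a source of variation that the labels do not name. Among siRNA samples the sets coincide with the agent, so an AT7519 change there cannot be told apart from a difference between sets. The replicate block over all samples gave 1605 for siOGT2 and 1224 for OSMI2 against Scr, 34 and 376 for the siOGT1 and OSMI2 interactions and 1069 for both siRNAs. The replicate block within agent and kind of arm gave 6560 and 4597 for siOGT1 and siOGT2 against Scr, 949 and 254 for their interactions and 3152 for both siRNAs. It was not used for the other comparisons, where its terms do not cancel. On its 4 libraries, AT7519 in siOGT2 gave 9426 genes with the replicate block and 10451 with the numbers crossed. Scaling to mitochondrially encoded genes was not run because all 13 are listed at 0. At 40216911 to 147019364 counts per library, depth limits genes below the filter, which were not tested.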

Other observations

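Single members of further lists changed under DMSO. With siOGT1, the chaperone gene HSP90AB1 fell by 0.64 and the small heat shock gene HSPB8 by 1.26, while HSPA4L rose by 0.66. With siOGT2, HSPB1 rose by 0.73. These members were picked for a small adjusted p and do not stand for their list. The heat shock list had a median of 0.012 with siOGT1 and -0.083 with siOGT2. The epididymal gene ADAM7 fell by 1.38 with siOGT1. KLK3 stood at 1052 CPM in Scr, 1294 in siOGT1 (0.299, adjusted p = 0.0896), 793.2 in siOGT2 (-0.407, adjusted p = 0.0381) and 1264 in OSMI2 (0.265, adjusted p = 0.230) under DMSO. The call of KLK3 with siOGT2 was lost without siOGT2 replicate 1 (adjusted p = 0.190) or 2 (0.214), Scr replicate 1 (0.129) or 2 (0.243), or siOGT1 replicate 1 (0.0523) or 2 (0.0522), all under DMSO.

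The most abundant gene was EEF1A1 in all 16 libraries, with 1.155% to 1.932% of counts. TMM factors were 0.864 to 0.952 with AT7519 and 1.048 to 1.131 with DMSO.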
